A study of Mus musculus with 9 samples.

How the data were processed

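Poly(A) RNA of leukemia-initiating cells from mouse bone marrow was measured in 9 samples. The authors deposited 1 table of raw read counts per gene, with 1 column per sample and no normalization, for 78298 unversioned Ensembl gene IDs. Per the submitters' processing notes, Trim Galore 0.5.0, Subread 2.0.6, featureCounts 2.0.6 and bedtools 2.31.1 were used, and the builds mm10 and GRCm39 are named without a role for each. Which annotation release, strand setting and rule for reads with several matches were used is not given in the sources used here. Per the labels' protocols, libraries were made with a kit based on the transposase Tn5, which does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

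Each sample was placed in its group by its title, because the treatment labels of the knockout samples differ in the gene symbol. Some read HMHCS2, HMGCS3 or HMGCS4 in place of HMGCS2, which was assumed to be a typing error and could not be checked in the reads. The groups were WT, KO and KO_BHB, with 3 samples each, and each column was matched to its sample by name. The samples held 36070261 to 47189206 counts each. Replicates of a group differed by more than sampling noise, with a chi-square per gene of 5.41 to 42.3 for pairs within a group, so no library was counted as a repeat of another.

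Gene symbols came from GENCODE M21 (GRCm38), which was used only for names, overlaps between genes, GC content and transcript length. Of the IDs, 51498 matched a symbol and 26800 did not, and the latter held 2.14% of all counts. The 13 mitochondrially encoded genes were listed at 0 in every sample and could not be tested. Among 280 genes looked at for overlaps, 77 share exon bases with another annotated gene, and 17 share at least 20% of them or have a partner with more reads. Those 17 are uncertain, among them Slc16a6, B4galnt1, Plppr3, Hspe1, Ankrd37, Dusp1, Gins2, Kif20a, Syvn1, Rpl35 and Ctsl. Ribosomal protein, ferritin and histone genes have copies that can share reads.

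Differential expression was tested with edgeR 4.0.16 in R 4.3.3. The fit used all 9 samples, TMM factors, filterByExpr by group and the quasi-likelihood test (glmQLFit and glmQLFTest) with group as the only term, which left 20563 genes. The common biological coefficient of variation was 0.148. P-values were adjusted by Benjamini-Hochberg over all tested genes, and an adjusted p of at most 0.05 counted as a call, for which "rose" and "fell" are used. All tests were two-sided.

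Before the data were examined, 38 gene lists were fixed, with 837 members of which 812 were found. They cover ketone and ferroptosis biology, metabolism, stress responses, cell cycle, myeloid stages, inflammation and other cell types of the marrow. Genes can belong to more than 1 list, so the lists are not independent. Fth1, Ftl1 and Slc40a1, for example, are both ferroptosis suppressors and iron and heme genes. The 35 lists with at least 5 tested genes were tested with camera of limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2), adjusted over the lists, and again with an estimated correlation and with fry. The genes to be named were also fixed by rule: for each comparison the 12 higher and 12 lower genes with the smallest p among those called with an absolute log2 fold change of at least 1, a mean of at least 5 CPM in the higher group, groups that did not overlap and a symbol that is not a clone or predicted name. To these were added the ketone body list, Gpx4, Slc7a11, Aifm2, Acsl4 and Tfrc, up to 4 members of each described list with the smallest p, and up to 6 genes per direction for the comparison of changes. Actb, S100a8 and Chil3, which are among the most abundant genes, were chosen after their values were seen.

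Because both comparisons of changes use the KO libraries, libraries with the KO mean levels in every group (unchanged groups) were simulated 20 times. Each group comparison was repeated over the 10 splits of its 6 samples. Alternatives fixed beforehand were DESeq2 1.42.0, RLE factors, no filter on low counts, a fit of the 6 samples of the 2 groups alone, the replicate number as a block, and leaving out each sample in turn. Library size alone, and a fit with the trend of each library with GC content and transcript length taken out (natural splines with 4 degrees of freedom, genes of at least 1 mean CPM), were added after seeing the data. The GC and length trend could be computed for 87.9% of tested genes.

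The steps were tested on simulated data. For the comparison of KO with WT (19331 genes), edgeR recovered 50.0% of 68 genes changed by 0.5 on the log2 scale, 81.8% of 66 changed by 1 and 97.0% of 66 changed by 2, with 7 false calls. Camera called the list of 30 genes that had been moved and 0 of 40 that had not. The simulated genes varied independently, so this does not test lists whose members vary together. Far fewer genes were changed than were called in the data, so scaling under such broad change was not tested either. A simulated GC trend gave 3709 false calls without the correction and 0 with it.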

Results

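Poly(A) RNA was sequenced from leukemia-initiating cells (LICs), the cells that can start the disease anew, of C57BL/6J mice with acute myeloid leukemia (AML). The 9 libraries formed 3 groups of 3: AML with intact Hmgcs2 (WT), AML with Hmgcs2 knocked out (KO), and the knockout given beta-hydroxybutyrate (KO_BHB). Hmgcs2 is the mitochondrial enzyme that controls the rate of ketone body synthesis, and beta-hydroxybutyrate is the main circulating ketone body. The comparisons address how LICs with the knockout differ from WT and which differences the ketone body turns back. Ferroptosis, an iron-dependent death through lipid peroxidation, is the named interest. The labels describe bone marrow that was flushed and cleared of red cells, and a sorting step was not given in the sources used here. How the ketone body was given, at what dose and for how long, and whether to the mice or to cells taken from them, was not given either. They do not say that the 3 libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

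The libraries held 36070261 to 47189206 counted reads, and 20563 genes passed the filter on low counts. Levels are given as mean ± SD in CPM (counts scaled to the TMM-adjusted library size) over the 3 libraries of a group, and log2 fold changes as estimate ± SE. Libraries of one group correlated at 0.977 to 0.989 and libraries of different groups at 0.885 to 0.963 (Pearson, log2 CPM, across genes). The first principal component, with 62.8% of the variance, separated WT from the other groups, and the second, with 18.7%, separated KO from KO_BHB. KO_BHB replicate 1 lay apart from its group on the third component (5.31% of the variance), at 54.5 against -32.9 and -36.0. The 10 most abundant genes took 15.5 to 16.4% of WT counts, 6.66 to 7.32% of KO counts and 10.4 to 10.7% of KO_BHB counts. In WT these included the neutrophil genes S100a8 (2.82% ± 0.203), Ngp (2.70% ± 0.157), S100a9 (2.07% ± 0.127) and Chil3 (2.05% ± 0.126). In KO_BHB the cytoskeletal gene Actb took 3.79% ± 0.392, against 1.73% ± 0.0611 in WT and 1.66% ± 0.132 in KO.

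**Figure D1:**
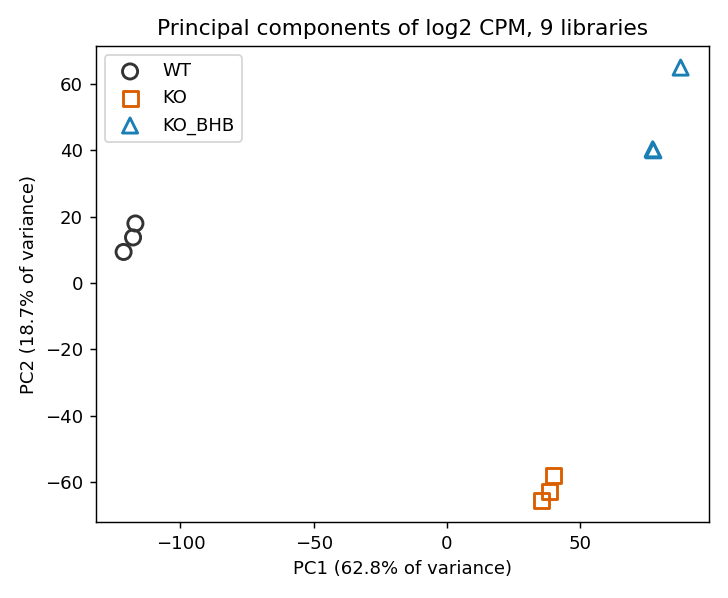
Principal components of log2 CPM, with PC1 on the x axis (62.8% of the variance) and PC2 on the y axis (18.7%). Each symbol is 1 of the 9 libraries, the 3 WT libraries lie between -121 and -117 on PC1, and all KO and KO_BHB libraries lie above 35.

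Hmgcs2 itself could not be used to check the knockout. It had 0, 0 and 0 reads in the WT libraries, 2, 0 and 4 in KO, and 0, 2 and 0 in KO_BHB. A count of 0 over all reads of the WT libraries allows a level of up to 0.0276 CPM (95% exact Poisson interval). The 6 reads in KO corresponded to 0.0525 CPM (95% exact Poisson interval 0.0192 to 0.114), and the 2 reads in KO_BHB to 0.0169 CPM (0.00204 to 0.0609). These limits cover counting error only. No fold change was computed, because WT held no reads and the gene did not pass the filter. At this depth Hmgcs2 transcripts were not detectable in the WT group, so its loss was not measurable as a drop in reads. These reads therefore do not show that ketone synthesis was lost in the KO cells. Bdh2 (20 reads in all 9 libraries) and Hmgcll1 (14 reads), also of the ketone body list, did not pass the filter either and were not tested.

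KO LICs were compared with WT LICs to see what differed in the knockout. Transcripts of neutrophil granules were far lower in KO: Ngp, a granule protein, went from 26289.8 ± 1537 to 696 ± 16.2 CPM, 37.8-fold lower. The antimicrobial genes Ltf and Camp fell 43.6-fold and 40.1-fold, the lectin Fcnb 52.6-fold, and the calprotectin subunit S100a9 from 20196 ± 1239 to 911 ± 12.8 CPM. Macrophage genes were higher: the chemokine Ccl2 rose 71.9-fold, from 18.7 ± 1.29 to 1341 ± 5.86 CPM, and arginase Arg1 rose 18.3-fold. The scavenger receptor Msr1 rose from 33.7 ± 0.697 to 537 ± 29.3 CPM, and the metalloelastase Mmp12 rose by 6.81 ± 0.12 on the log2 scale. Spp1 (osteopontin) and the lipase Lpl rose 37.2-fold and 48.7-fold.

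The gene lists were fixed before the data were examined, and unless another count is given, the counts of rises and falls were the same adjusted over the list alone. In the list of late neutrophil genes 0 rose and 19 fell of 20 tested, with a median log2 fold change of -4.36. The camera adjusted p was 4.79e-15, and the adjusted p was 0.0838 with an estimated correlation, which ends the call. Of the monocyte and macrophage genes, 16 rose and 6 fell of 23 tested, with a median of 2.21 (camera adjusted p 0.000465, adjusted p 0.198 with an estimated correlation). The chemokine Ccl6 (3.85 ± 0.0825), the transcription factor Irf8 (2.33 ± 0.0553) and the complement gene C1qb (3.65 ± 0.0940) were among those that rose. Earlier granule and progenitor genes went both ways: 6 rose and 7 fell of 15 tested, camera adjusted p 0.674. Mpo, the myeloperoxidase of primary granules, fell by 3.08 ± 0.0764 on the log2 scale, while Ctsg, a granule protease, rose (0.72 ± 0.0492).

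Markers of other marrow cells went different ways, and none of their lists was called. The antibody genes Igha and Jchain were at 18.5 ± 1.16 and 8.69 ± 0.481 CPM in WT and at 0.0331 ± 0.0573 and 0.339 ± 0.0795 CPM in KO. In the plasma cell list 1 rose and 6 fell of 8 tested, with a camera adjusted p of 0.05004 that fell under the threshold when any 1 of the 6 WT and KO libraries was left out (0.0277 to 0.0484). It was also under the threshold with RLE scaling (0.0450), library size alone (0.0285) or no filter on low counts (0.000908). Its adjusted p was 0.282 with an estimated correlation. Cpa3, a mast cell protease, rose (4.01 ± 0.12) while the eosinophil granule genes Prg2 (-1.21 ± 0.18) and Epx (-7.57 ± 1.16) fell. Over that list of mast cells, basophils and eosinophils 1 rose and 4 fell of 7 tested, camera adjusted p 0.233. Erythroid genes (2 rose and 3 fell of 7 tested) and B lineage genes (2 rose and 2 fell of 7 tested) were not called, with camera adjusted p of 0.674 and 0.901. The platelet chemokines Ppbp (6.77 ± 0.0902) and Pf4 (3.60 ± 0.0687) rose, whereas the platelet receptor genes Itgb3 (-1.79 ± 0.23) and Gp9 (-3.25 ± 0.70) fell. That list had 2 rises and 2 falls of 7 tested (the same adjusted over the list alone), a negative median (-0.72), a positive mean (0.39) and a camera adjusted p of 0.807. T and NK genes (4 tested) and stromal genes (3 tested) were too few for a list test.

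**Figure D2:**
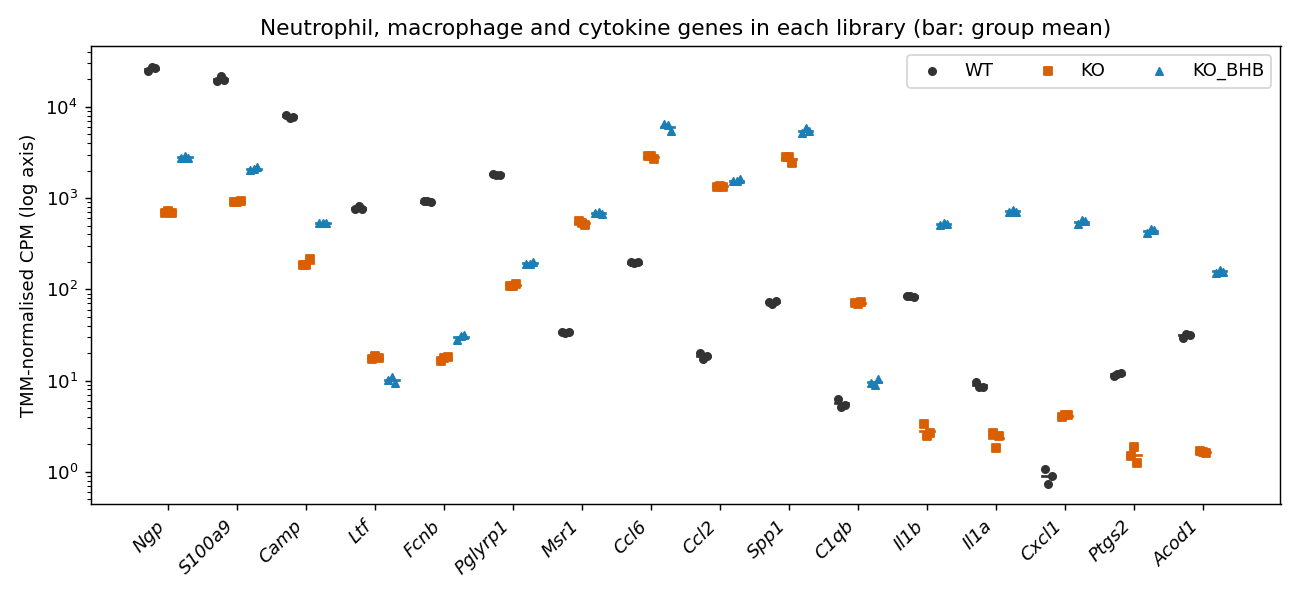
Levels of neutrophil, macrophage and cytokine genes in each library, in TMM-normalised CPM on a log axis, with a bar at each group mean. Ngp is at 26290 CPM in WT, 696 in KO and 2823 in KO_BHB, and Il1b is at 83.6, 2.81 and 523 CPM.

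Nuclear genes of mitochondrial energy metabolism were modestly higher in KO. Of the nuclear genes for oxidative phosphorylation subunits, 40 rose and 1 fell of 51 tested, 41 and 1 adjusted over the list alone, with a median of 0.40. Sdhb (0.84 ± 0.0586) and Uqcrq (0.83 ± 0.0719) were examples. The tricarboxylic acid cycle list had a similar median of 0.42, and 17 rose and 0 fell of 22 tested. Cytosolic ribosomal protein genes followed with a median of 0.45, and 26 rose and 0 fell of 40 tested, 28 and 0 adjusted over the list alone, although many have pseudogene copies that can share reads. Camera adjusted p for these 3 lists was 5.59e-07, 0.000181 and 7.06e-05, and the adjusted p was 0.421, 0.531 and 0.531 with an estimated correlation. After the GC and length trend was taken out, their medians were 0.32, 0.41 and 0.38, and camera still called them. Short transcripts were higher in general, with a median of 0.30 in the fifth of genes with the shortest.

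Fatty acid oxidation genes (11 rose and 3 fell of 22 tested) and fatty acid synthesis and activation genes (11 rose and 3 fell of 19 tested) were both called, with camera adjusted p of 0.0406 and 0.0411. The elongase Elovl6 (2.23 ± 0.0700) and the desaturase Fads1 (1.52 ± 0.11) rose, and the acyl-CoA synthetase Acsl1 (-1.16 ± 0.0651) fell. With an estimated correlation the adjusted p was 0.531 and 0.439. The oxidation call ended without KO replicate 2 (adjusted p 0.0508), and the synthesis call ended without WT replicate 1 (0.0533) or KO replicate 2 (0.0511). Cholesterol synthesis genes were not called (camera adjusted p 0.718), and 7 rose and 7 fell of 23 tested. Glucose genes pointed down without passing as a list: 2 rose and 9 fell of 21 tested, camera adjusted p 0.0592. That list passed with no filter on low counts (adjusted p 0.00910) and without WT replicate 3 (0.0440). The glucose transporter Slc2a3 fell 53.6-fold, from 436 ± 16.1 to 8.12 ± 0.483 CPM, and Pfkfb4, a regulator of glycolysis, fell (-2.24 ± 0.13). Hypoxia-response genes were lower as a list: 1 rose and 13 fell of 19 tested, with a median of -0.62 (camera adjusted p 0.00221, adjusted p 0.0838 with an estimated correlation). Bnip3l (-1.20 ± 0.0507) and the oxygen sensor Egln3 (-1.07 ± 0.0492) were among them.

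Of the ketone body genes, 5 rose and 2 fell of 9 tested, and the list was not called (camera adjusted p 0.165). Bdh1, which interconverts beta-hydroxybutyrate and acetoacetate, rose 4.95-fold from a low level, 1.54 ± 0.297 to 7.62 ± 0.570 CPM. The ketone-using enzymes Oxct1 (0.46 ± 0.0792) and Acat1 (0.46 ± 0.0636) and the transporters Slc16a1 (0.84 ± 0.0730) and Slc16a7 (1.76 ± 0.14) also rose. Acat2 (-0.30 ± 0.0708) and Aacs, which activates acetoacetate in the cytosol (-0.28 ± 0.0868), fell. The Aacs call ended with library size alone (adjusted p 0.102), after the trend with GC content and length was taken out (0.0528), and without WT replicate 1 (0.0615), WT replicate 3 (0.0537) or KO replicate 1 (0.0916). Hmgcl, the last enzyme of ketone synthesis, gave -0.12 ± 0.0712 (adjusted p 0.176) and Slc16a6 -0.08 ± 0.0571 (adjusted p 0.288), and neither was called by edgeR. Hmgcl passed after the GC and length trend was taken out (-0.15, adjusted p 0.0311). Slc16a6 shares 21.5% of its exon bases with Amz2, so its reads are uncertain.

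Ferroptosis suppressors were called as a list: 13 rose and 4 fell of 24 tested, with a median of 0.36. The camera adjusted p was 0.0177, and the adjusted p was 0.421 with an estimated correlation. The acyltransferase Mboat1 (1.81 ± 0.0743) and Gch1, which starts tetrahydrobiopterin synthesis (1.37 ± 0.0864), rose, and the quinone reductase Nqo1 (-1.60 ± 0.0853) and the iron exporter Slc40a1 (-1.12 ± 0.0755) fell. The cystine importer subunit Slc7a11 rose 1.53-fold, from 15.9 ± 1.90 to 24.3 ± 0.703 CPM. Gpx4, the lipid peroxide reductase at the centre of ferroptosis defence, was at 215 ± 26.0 CPM in WT and 201 ± 17.5 in KO (-0.10 ± 0.19, edgeR adjusted p 0.696). Aifm2, which encodes the suppressor FSP1, gave 0.12 ± 0.0827 (adjusted p 0.236), and it passed with library size alone (0.22, adjusted p 0.0421) and after the GC and length trend was taken out (0.20, adjusted p 0.0409). Ferroptosis drivers and markers went both ways: 9 rose and 10 fell of 24 tested, 9 and 12 adjusted over the list alone, camera adjusted p 0.648. The heme oxygenase Hmox1 rose from 32.3 ± 1.76 to 135 ± 4.11 CPM and the acyl-CoA synthetase Acsl4 rose 1.45-fold. Ptgs2 (-2.92 ± 0.11), Alox5 (-1.84 ± 0.11) and Cybb (-1.82 ± 0.0656) fell. The transferrin receptor Tfrc gave -0.06 ± 0.0853 (adjusted p 0.562). Iron and heme, NRF2 target, and glutathione and peroxide lists were not called, with camera adjusted p of 0.165, 0.205 and 0.0572. The last of these passed with no filter on low counts (0.0292). Their counts were 10 rose and 5 fell of 24 tested, 13 rose and 7 fell of 22 tested, 13 and 8 adjusted over the list alone and 17 rose and 7 fell of 30 tested, 18 and 7 adjusted over the list alone.

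**Figure D3:**
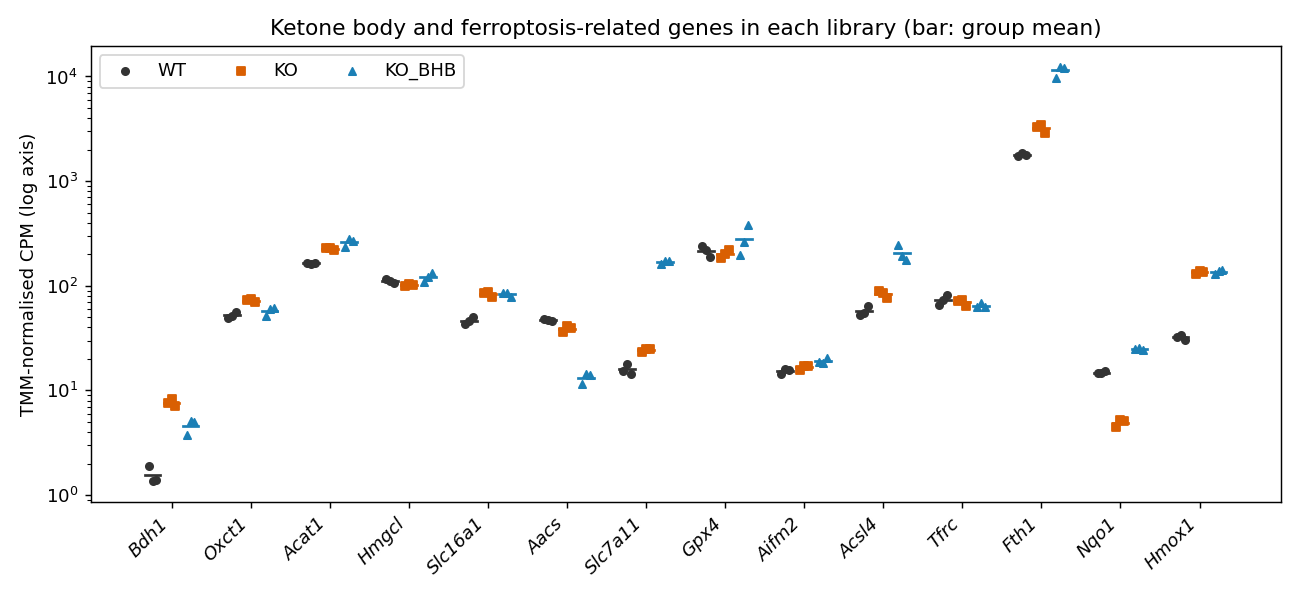
Levels of ketone body and ferroptosis-related genes in each library, in TMM-normalised CPM on a log axis, with a bar at each group mean. Bdh1 is at 1.54 CPM in WT, 7.62 in KO and 4.61 in KO_BHB, and Slc7a11 is at 15.9, 24.3 and 169 CPM.

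Interferon-response genes were lower in KO. In that list 2 rose and 22 fell of 30 tested, with a median of -1.02 (camera adjusted p 9.75e-06, adjusted p 0.0838 with an estimated correlation). The antiviral genes Rsad2 (-3.35 ± 0.12) and Oas3 (-2.24 ± 0.0942) fell and Gbp3 (2.17 ± 0.0754) rose. Stress-response genes rose as lists: heat shock (9 rose and 0 fell of 11 tested), ATF4 targets (15 rose and 4 fell of 22 tested) and the unfolded protein response (13 rose and 2 fell of 20 tested). Hsph1 (1.14 ± 0.0714), the amino acid enzymes Cth (2.41 ± 0.0935) and Asns (1.21 ± 0.0546), and Edem1 (1.14 ± 0.0574) were examples. Camera adjusted p was 0.00132, 0.00199 and 0.0177, and the adjusted p was 0.0838, 0.198 and 0.439 with an estimated correlation. Core histone genes, which poly(A) libraries capture poorly, had a median of -0.86, and 0 rose and 7 fell of 16 tested (camera adjusted p 0.0182, adjusted p 0.421 with an estimated correlation). Genes of stem cells and leukemia self-renewal were not called as a list (camera adjusted p 0.901), and 8 rose and 9 fell of 24 tested, 9 and 10 adjusted over the list alone. The receptor Kit fell from 41.9 ± 2.25 to 4.47 ± 0.421 CPM and the homeobox gene Meis1 fell too (-1.52 ± 0.0609), while Cd34 rose from 9.12 ± 1.52 to 79.3 ± 1.36 and Gata2 from 2.01 ± 0.611 to 16.4 ± 0.663.

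In all, edgeR's quasi-likelihood test called 11232 of 20563 genes between KO and WT, 5536 higher and 5696 lower. Changes of at least 2-fold numbered 1876 higher and 2981 lower, and changes of at least 10-fold 366 and 478. The groups did not overlap in 64.6% of tested genes, where chance gives 10%. Adjusted p for the 24 genes named by rule ran from 4.79e-12 to 2.98e-11. Camera called 14 of 35 lists, and no list call held with an estimated correlation, except that of the interferon list with library size alone (adjusted p = 0.0399). Scaling by library size alone moved the median of all genes by 0.10 on the log2 scale. Over 10446 genes with a mean of at least 5 CPM, Spearman's rho of fold change was -0.0589 with GC content and -0.217 with transcript length. The median log2 fold change was 0.30 in the fifth of genes with the shortest transcripts and -0.12 in the fifth with the longest.

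KO_BHB was compared with KO to see what the ketone body changed in the knockout. Inflammatory cytokine genes were much higher with BHB. Il1b, the main secreted interleukin-1, went from 2.81 ± 0.459 to 523 ± 15.4 CPM, 186-fold higher, and Il1a from 2.33 ± 0.453 to 721 ± 24.7 CPM. The prostaglandin synthase Ptgs2 rose 286-fold, the neutrophil chemokines Cxcl1 and Cxcl2 133-fold and 23.4-fold, and the itaconate-making enzyme Acod1 94.8-fold. The macrophage chemokines Ccl3 and Ccl4 and the lipopolysaccharide co-receptor Cd14 rose 21.0-fold, 19.2-fold and 13.2-fold. Lower with BHB were the monocyte chemokine Ccl12 (28.5-fold), the complement gene C1qb (7.30-fold), the lysosomal protease Lgmn (4.26-fold) and Mpo (4.09-fold).

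In the list of NF-kB targets and inflammatory cytokines 22 rose and 2 fell of 26 tested, with a median log2 fold change of 1.80. The camera adjusted p was 6.53e-12 and stayed under the threshold with an estimated correlation (adjusted p = 0.00820), the only list of this comparison for which it did. After the GC and length trend was taken out, the interferon, hypoxia and cholesterol lists passed with an estimated correlation as well (adjusted p = 0.0398 for each). With library size alone all genes of this comparison shift by about -0.32, and the list medians with them. Immediate early genes, which respond within minutes to many stimuli, moved with the cytokine list: 11 rose and 1 fell of 17 tested (camera adjusted p 0.0131, adjusted p 0.355 with an estimated correlation), with Atf3 (2.02 ± 0.10) and Nr4a1 (1.67 ± 0.24) as examples. With library size alone 7 of them rose and 5 fell. Interferon-response genes were lower again: 2 rose and 20 fell of 30 tested, 2 and 21 adjusted over the list alone, with a median of -0.64 (camera adjusted p 5.19e-05, adjusted p 0.0693 with an estimated correlation). Oasl2 went from 6.51 ± 0.682 to 0.762 ± 0.280 CPM. Macrophage genes as a list were not called (camera adjusted p 0.542), and 9 rose and 11 fell of 23 tested. Late neutrophil genes rose in part, and 11 rose and 6 fell of 20 tested, with a median of 0.61 (camera adjusted p 0.00857, adjusted p 0.505 with an estimated correlation), or 0.28 with library size alone. Ngp went from 696 ± 16.2 to 2823 ± 72.1 CPM and Lcn2 from 108 ± 4.56 to 678 ± 78.6, against 26289.8 ± 1537 and 3621 ± 135 in WT. Of the MHC class II genes 6 rose and 1 fell of 10 tested, 7 and 1 adjusted over the list alone, with a camera adjusted p of 0.0250 (adjusted p 0.505 with an estimated correlation), a call that ended with library size alone (0.0664) and without KO_BHB replicate 3 (0.0543).

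Ferroptosis-related genes included large changes in both directions. Among suppressors Slc7a11 rose 6.93-fold, from 24.3 ± 0.703 to 169 ± 5.16 CPM, and the ferritin heavy chain Fth1 from 3201 ± 288 to 11427 ± 1512. Nqo1 (2.35 ± 0.0864) rose as well, and Scd2 (-0.87 ± 0.0601) fell. Among drivers and markers Ptgs2 (8.16 ± 0.12) and Acsl4 (1.31 ± 0.13) rose, and Steap3 (-2.06 ± 0.15) and Chac1 (-1.43 ± 0.14) fell. Fth1 has pseudogene copies that can share its reads. Of the ferroptosis suppressors 10 rose and 5 fell of 24 tested, 12 and 5 adjusted over the list alone, and the list was not called (camera adjusted p 0.0757). It passed after the GC and length trend was taken out (adjusted p 0.00713), with no filter on low counts (0.0462), and without KO replicate 2 (0.0442) or KO_BHB replicate 1 (0.0381). Gpx4 was at 201 ± 17.5 CPM in KO and 279 ± 93.8 in KO_BHB (0.47 ± 0.19, edgeR adjusted p 0.0655), and without KO_BHB replicate 1 it passed at 0.67 (adjusted p 0.00335). It also passed with DESeq2 (adjusted p 0.0194), without the filter on low counts (5.06e-08) and after the GC and length trend was taken out (0.0269). The median of the list turned to -0.16 with library size alone. Aifm2 gave 0.20 ± 0.0828 (adjusted p 0.0672), turned to -0.12 with library size alone, and passed with RLE scaling (0.22, adjusted p 0.0474) and after that trend was taken out (0.59, adjusted p 9.52e-05). Tfrc gave -0.12 ± 0.0857 (adjusted p 0.284) and passed with library size alone (-0.44, adjusted p 0.000953) and after the trend was taken out (-0.26, adjusted p 0.00692). Drivers and markers of ferroptosis were not called as a list (camera adjusted p 0.483), and 5 rose and 9 fell of 24 tested, with a median of -0.17 and a mean of 0.15. Glutathione and peroxide enzymes were called: 16 rose and 2 fell of 30 tested, among them the superoxide dismutase Sod2 (2.01 ± 0.0508), with a camera adjusted p of 0.000381 and an adjusted p of 0.181 with an estimated correlation. The median went from 0.43 to 0.23 after the GC and length trend was taken out, and to 0.11, with 11 rises and 9 falls, with library size alone. For NRF2 targets 11 rose and 4 fell of 22 tested (camera adjusted p 0.0182, adjusted p 0.505 with an estimated correlation), and the median turned from 0.22 to -0.10 with library size alone (adjusted p 0.116).

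Of the ketone body genes 2 rose and 4 fell of 9 tested, 3 and 4 adjusted over the list alone, and the list was not called (camera adjusted p 0.432). Aacs fell 2.92-fold, and Bdh1 (-0.72 ± 0.17), Oxct1 (-0.32 ± 0.0793) and Slc16a6 (-0.42 ± 0.0578) also fell. Hmgcl (0.25 ± 0.0713) and Acat1 (0.20 ± 0.0634) rose, but with library size alone their estimates turned to -0.07 and -0.12 (adjusted p 0.420 and 0.121). Acat1 also lost its call without any 1 of 5 libraries, all but KO_BHB replicate 1 of the 6 compared (adjusted p 0.0508 to 0.0996), and Hmgcl without KO replicate 1 (0.0610) or KO_BHB replicate 3 (0.0584). Both lost it with no filter on low counts (0.195 and 0.0779) and in a fit of the 6 libraries alone (0.0893 and 0.0571). Slc16a1 gave 0.00 ± 0.0723 (adjusted p 0.980), and -0.32 with library size alone (adjusted p 0.00244). The remaining members were not called, with Slc16a7 at -0.21 ± 0.13 (adjusted p 0.227, but 0.00679 with library size alone) and Acat2 at 0.18 ± 0.0713 (adjusted p 0.0613, but 0.0440 with RLE scaling and 0.0386 after the GC and length trend was taken out). Fatty acid synthesis and activation genes were lower: 1 rose and 14 fell of 19 tested, with a median of -0.53, or -0.33 after the GC and length trend was taken out (camera adjusted p 0.000641, adjusted p 0.308 with an estimated correlation). The fatty acid synthase Fasn (-1.51 ± 0.12) and the regulator Srebf1 (-1.22 ± 0.0869) fell. Among cholesterol synthesis genes 16 rose and 5 fell of 23 tested (camera adjusted p 0.0240, adjusted p 0.404 with an estimated correlation), and the median turned from 0.31 to -0.01 with library size alone, where the list was not called.

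Of the oxidative phosphorylation genes 36 rose and 6 fell of 51 tested, 37 and 6 adjusted over the list alone and ribosomal protein genes 23 rose and 1 fell of 40 tested, 24 and 1 adjusted over the list alone. With library size alone these became 22 rises against 14 falls and 4 against 6, through the shift of all genes alike. With the GC and length trend taken out, 23 oxidative phosphorylation genes rose and 6 fell, and the median went from 0.44 to 0.18. Camera adjusted p was 4.87e-06 and 0.00117, and the adjusted p was 0.505 and 0.595 with an estimated correlation. Glycolysis genes were lower (4 rose and 13 fell of 21 tested, 4 and 14 adjusted over the list alone), among them Hk3 (-1.37 ± 0.0674) and the lactate exporter Slc16a3 (-1.38 ± 0.0822), with a camera adjusted p of 0.00857 and an adjusted p of 0.588 with an estimated correlation. That call ended after the GC and length trend was taken out, where the median went from -0.53 to -0.29 (adjusted p 0.215). Replication genes (6 rose and 15 fell of 24 tested, 6 and 16 adjusted over the list alone) and mitotic genes (3 rose and 13 fell of 24 tested) were lower too, with camera adjusted p of 0.00857 and 0.0148, and an adjusted p of 0.505 for each with an estimated correlation. The replication median went from -0.50 to -0.28 after the GC and length trend was taken out. The helicase subunit Mcm3 (-0.98 ± 0.0575) and the mitotic kinase Plk1 (-1.37 ± 0.0999) were examples. The list of stem cells and leukemia self-renewal was not called (camera adjusted p 0.734), and 4 rose and 7 fell of 24 tested. Targets of p53 (12 rose and 3 fell of 20 tested) and hypoxia-response genes (10 rose and 4 fell of 19 tested) rose as lists, with camera adjusted p of 0.00857 and 0.00998, and an adjusted p of 0.355 and 0.181 with an estimated correlation. With library size alone both lists were still called, but 9 p53 targets rose and 6 fell (median 0.17), and 8 hypoxia genes rose and 7 fell (median 0.11). The death receptor Fas (2.29 ± 0.0564) and the cell cycle inhibitor Cdkn1a (1.07 ± 0.0481) rose among the p53 targets.

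edgeR called 9748 genes between KO_BHB and KO, 4873 higher and 4875 lower. With library size alone, which moved the median of all genes by -0.32, the split was 2426 higher and 7987 lower, so the balance of rises and falls rests on the scaling. Changes of at least 2-fold numbered 1463 higher and 1510 lower, and changes of at least 10-fold 129 and 43. The groups did not overlap in 54.8% of genes, where chance gives 10%. Adjusted p for the 24 genes named by rule ran from 5.71e-12 to 4.74e-08. Fold changes followed transcript properties across genes: over 10446 genes with a mean of at least 5 CPM, Spearman's rho was -0.356 with GC content and -0.301 with transcript length. The median log2 fold change was 0.28 in the fifth of genes with the lowest GC content and -0.40 in the fifth with the highest. Genes are not independent replicates, so no p is given. Camera called 16 of 35 lists, and 16 after the GC and length trend was taken out.

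**Figure D4:**
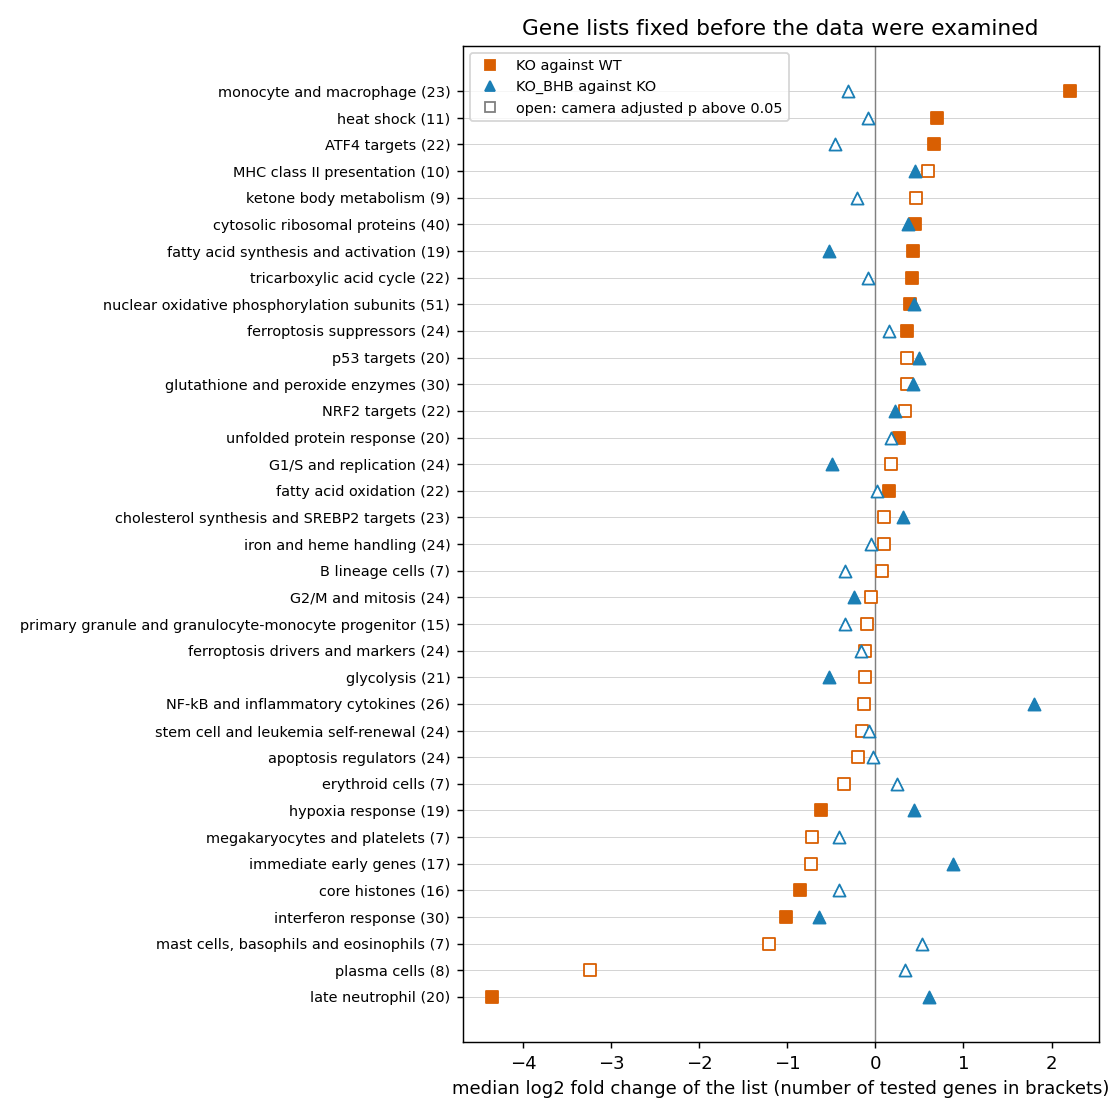
Median log2 fold change of each of the 35 tested gene lists (x axis) for KO against WT (squares) and KO_BHB against KO (triangles), with filled symbols for a camera adjusted p of at most 0.05 and open symbols above it. Late neutrophil genes are at -4.36 in KO against WT, and NF-kB and cytokine genes are at 1.80 in KO_BHB against KO, and with library size alone the medians of NRF2 targets, cholesterol synthesis and ferroptosis suppressors turned negative in KO_BHB against KO.

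The next comparison asked which changes of the knockout went back with BHB. Of the 11232 genes called between KO and WT, 2800 (24.9%) were called the opposite way between KO_BHB and KO, and 3315 (29.5%) were called again in the same direction. The 6 genes named by rule for a rise in KO and a fall with BHB were the monocyte chemokine Ccl12, the complement genes C1qa, C1qb and C1qc, Lgmn and Pld4. Ccl12 was at 0.232 ± 0.108, 89.1 ± 5.27 and 3.12 ± 0.309 CPM in WT, KO and KO_BHB, and C1qb at 5.62 ± 0.617, 70.5 ± 1.75 and 9.65 ± 0.757. The chemokine gene Ccl4, in contrast, rose in both comparisons. The 6 genes named for a fall in KO and a rise with BHB were Il1b, Acod1, Saa3, Arg2, Fpr1 and Fas. Il1b was at 83.6 ± 1.62, 2.81 ± 0.459 and 523 ± 15.4 CPM, and Acod1 at 31.2 ± 1.63, 1.65 ± 0.0614 and 157 ± 4.83. Fas ended at 79.0 ± 1.51 CPM against 73.4 ± 1.04 in WT (0.11 ± 0.0527, adjusted p 0.0962). That difference passed as higher with DESeq2 (adjusted p 0.0405) and RLE scaling (0.0351), and turned to -0.42 after the GC and length trend was taken out (1.06e-05). The list of NF-kB targets and cytokines went both ways in KO against WT (9 rose and 12 fell of 26 tested, camera adjusted p 0.674). Others moved further from WT. Serpinb2 rose from 5.98 ± 0.509 to 80.1 ± 9.20 and 1614 ± 29.9 CPM, and Mpo fell from 1104 ± 28.5 to 130.4 ± 7.15 and 31.9 ± 3.07.

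Of the genes called in KO, 8775 (78.1%) were still called against WT in the same direction after BHB. The number that went the opposite way and were no longer called against WT was 1118. By direction, 1441 genes rose in KO and fell with BHB, where independent lists of these sizes would share 1312. Genes that fell and then rose numbered 1359 against 1350 for independent lists, genes that rose in both 1768 against 1312, and genes that fell in both 1547 against 1350. Every class lay above its value, so an excess over independent lists does not single out a reversal. With BHB, 43.2% of the genes called higher in KO and 46.3% of those called lower stood nearer to WT than in KO. Among those changed at least 2-fold the shares were 53.3% and 53.8%. Simulated unchanged groups, in which no gene differs, gave 0 in each class over 20 simulations, which says nothing of genes that did change. The log2 fold changes correlated at -0.117 across genes (-0.0859 to -0.186 when 1 library was left out, and -0.157 to -0.186 without KO replicate 1, 2 or 3, the last of these the strongest, and -0.359 with no filter on low counts). Simulated unchanged groups, which share a simulated KO group, gave -0.496 (SD 0.00896). Sharing a group gives a value near this wherever only noise is present, so it is no scale for genes that changed. The covariance was -0.158 against a simulated -0.0485, a difference of -0.110. The simulated covariance holds the sharing as far as the simulated spread matches the real one. No split of 3 KO libraries leaves 2 on each side, and none was run, so part of any excess may come from sharing them.

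KO_BHB was compared with WT to see what differed once BHB was given. Several macrophage genes stayed far above WT and neutrophil genes far below: Ccl2 was 83.5-fold higher than in WT, Msr1 20.2-fold and Spp1 76.4-fold, at 5497 ± 313 CPM. Ltf was 76.4-fold lower, Fcnb 30.3-fold and Camp 14.6-fold, and the granulocyte transcription factor Cebpe 7.34-fold. The chemokine genes Ccl4 and Cxcl1 stood far above WT, with Ccl4 at 54.9 ± 2.86 CPM in WT and 4262 ± 79.8 in KO_BHB, and Cxcl1 607-fold higher. The interferon-response genes Rtp4 and Oas3 were lower than in WT (-4.86 ± 0.10 and -4.78 ± 0.11). Slc7a11 was 10.6-fold higher than in WT and Bdh1 was higher too (1.59 ± 0.18), while Aacs was 3.54-fold lower.

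Interferon-response genes (3 rose and 25 fell of 30 tested, median -1.99) and NF-kB and cytokine genes (19 rose and 7 fell of 26 tested, median 1.65) were the 2 lists whose call held with an estimated correlation (adjusted p = 0.0419 for each, but 0.0568 for each after the GC and length trend was taken out, camera adjusted p 3.21e-06 and 8.36e-06). Of the late neutrophil genes 1 rose and 19 fell of 20 tested, with a median of -3.39 (camera adjusted p 1.56e-09, adjusted p 0.233 with an estimated correlation). Igha was at 0.0417 ± 0.0723 CPM and Jchain at 0.366 ± 0.0804, as low as in KO. Monocyte and macrophage genes (13 rose and 7 fell of 23 tested, 13 and 8 adjusted over the list alone) and MHC class II genes (7 rose and 1 fell of 10 tested) were higher, with a camera adjusted p of 0.0226 for each and an adjusted p of 0.419 and 0.436 with an estimated correlation. The median of the monocyte and macrophage list was 0.89, against 2.21 in KO against WT. The complement genes C1qb (0.78 ± 0.0922) and C1qc (1.07 ± 0.14) were higher than in WT, by less than in KO. C1qa gave 0.34 ± 0.17 (adjusted p 0.0972) and passed without KO_BHB replicate 2 (0.00958) and after the GC and length trend was taken out (0.0295). Oxidative phosphorylation genes (45 rose and 1 fell of 51 tested) and ribosomal protein genes (39 rose and 0 fell of 40 tested) were higher at medians of 0.76 and 0.79, with camera adjusted p of 7.62e-10 and 2.44e-07, and an adjusted p of 0.338 and 0.422 with an estimated correlation. The oxidative phosphorylation median was 0.48 and the ribosomal protein median 0.55 after the GC and length trend was taken out. Glycolysis genes were lower (2 rose and 16 fell of 21 tested, median -0.78, or -0.41 after that trend was taken out, camera adjusted p 0.00176, adjusted p 0.466 with an estimated correlation).

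Ferroptosis suppressors (17 rose and 4 fell of 24 tested), NRF2 targets (16 rose and 5 fell of 22 tested) and glutathione and peroxide enzymes (22 rose and 5 fell of 30 tested) were higher than in WT. Camera adjusted p was 0.00401, 0.0127 and 0.000744, and the adjusted p was 0.338, 0.419 and 0.233 with an estimated correlation. The last 2 of these lists had the same median, 0.669588. Genes can belong to more than 1 list, so the calls are not separate lines of evidence. Aifm2 was higher (0.32 ± 0.0828, adjusted p 0.00501), a call that ended with library size alone (0.10, adjusted p 0.288). Gpx4 gave 0.37 ± 0.19 (edgeR adjusted p 0.106) and passed without KO_BHB replicate 1 (0.58, adjusted p 0.00517). It also passed with DESeq2 (0.0404), without the filter on low counts (5.62e-06) and after the GC and length trend was taken out (0.0303). Ferroptosis drivers and markers (7 rose and 14 fell of 24 tested, camera adjusted p 0.425) and ketone body genes (4 rose and 2 fell of 9 tested, camera adjusted p 0.413) were not called.

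edgeR called 14066 genes between KO_BHB and WT, 6758 higher and 7308 lower, of which 3425 and 4331 changed at least 2-fold and 464 and 496 at least 10-fold. The groups did not overlap in 72.5% of genes, where chance gives 10%. Adjusted p for the 24 genes named by rule ran from 1.86e-12 to 5.11e-11. Camera called 16 of 35 lists. Those not yet given were the unfolded protein response (12 rose and 3 fell of 20 tested), heat shock (8 rose and 1 fell of 11 tested), p53 targets (11 rose and 5 fell of 20 tested), mitotic genes (5 rose and 17 fell of 24 tested) and core histones (1 rose and 8 fell of 16 tested), with camera adjusted p of 0.0313, 0.0254, 0.0403, 0.0251 and 0.0254. Their adjusted p was 0.436, 0.243, 0.419, 0.436 and 0.419 with an estimated correlation. The unfolded protein response call ended with library size alone (adjusted p 0.148) and the p53 call without KO_BHB replicate 2 (0.0509). Rho with GC content was -0.276 and with transcript length -0.326 across genes, and library size alone moved the median of all genes by -0.22.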

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

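No group has 4 or more samples, so no sample was tested for standing apart from its group. In the patterns weighed here, the tests of a loss of neutrophils alone, of more monocytes or macrophages, of handling and of a coverage bias, and the correction for GC content and length, were chosen after the results were seen. For each comparison the 6 samples allow only 10 splits into 3 and 3, too few for a share under 0.05. The real split called 11232 genes for KO against WT, 9748 for KO_BHB against KO and 14066 for KO_BHB against WT, and the highest of the other splits called 0 each time.

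The first pattern is the fall of late neutrophil genes in KO. The tables argue against scaling as the cause, since the median log2 fold change of the list was -4.36 and, under the scaling that brought it nearest to 0, -4.26. They also argue against GC content and transcript length, with a median of -4.43 after that trend was taken out. A loss of neutrophils alone would raise all other genes by a common amount. Called genes of the stem cell and leukemia self-renewal list went both ways, with 8 higher and 9 lower. All tested genes split much alike, with 5536 higher and 5696 lower, since the scaling centres fold changes near 0 (median -0.0230). The near-even split itself therefore decides nothing, and with library size alone 9 of the list rose and 6 fell. Changes of at least 2-fold in the list also went both ways, with 3 higher and 5 lower. A common amount would not give these under any scaling, if neutrophils make none of these genes. The antibody gene Igha went from 18.5 ± 1.16 CPM in WT to 0.0331 ± 0.0573 in KO, and Jchain from 8.69 ± 0.481 to 0.339 ± 0.0795. In the plasma cell list 1 rose and 6 fell of 8 tested, just short of a call (camera adjusted p 0.05004). These values go with a shift in cell content, but they do not show that it explains the neutrophil genes. A shift among several cell populations of the marrow and a change within the leukemic cells after the knockout both remain open, the latter as an untested hypothesis.

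The second pattern is the rise of NF-kB and cytokine genes with BHB. The trend with GC content and length is not the whole cause, since the median went only from 1.80 to 1.76 after it was taken out. A rise of all monocytes and macrophages alike would raise their marker genes together, but 11 called members of that list were lower in KO_BHB and 9 higher. A shift among several cell populations can raise some of these genes and lower others, so it was not tested by this and stays open. Activation of the cells during handling stays open and cannot be told apart from the treatment: 11 immediate early genes rose and 1 fell (7 and 5 with library size alone), and all KO_BHB libraries belong to 1 group. A response to BHB is the biological explanation that the design offers, and no test here separates it from handling or from such a shift.

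The third pattern is that fold changes of KO_BHB against KO followed GC content. Without the genes of the 38 lists, 9879 of 10446 genes remained, and Spearman's rho was -0.362, against -0.356 with them. So few genes were taken out that rho could hardly have changed, and the lists need not hold whole gene families. Whether these families contribute was therefore not decided. A coverage bias that differs between libraries remains a candidate explanation. Libraries of 1 group differed along GC content by a slope of up to 0.149 in log2 CPM per 10% of GC, against a slope of -0.388 between the groups. The 9 pairs of a KO_BHB and a KO library had slopes from -0.540 to -0.254, beyond every pair within a group, so a difference in the RNA itself may contribute, and group and library preparation cannot be separated.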

How the results depend on the processing

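Library size alone, and the fit with the GC and length trend taken out, were added after seeing the data, and the other alternatives were planned. Counts of called genes stayed within 1.5 times under every alternative run, except the split of KO_BHB against KO with library size alone, 2426 higher and 7987 lower, which follows from the shift of -0.32 in the median. With the GC and length trend taken out, 10236, 8442 and 12200 genes were called, and they shared 9469 of 10128, 6765 of 9206 and 10518 of 12773 calls among genes in both fits. With 1 sample left out, the counts ran from 9847 to 12249, from 8300 to 9514 and from 13046 to 14329, and the genes called in opposite ways from 2190 to 2846. The correlation of fold changes ran from -0.186 (without KO replicate 3) to -0.0859 (without KO_BHB replicate 2), and was -0.359 with no filter on low counts, where genes with few reads enter. Called lists numbered 14, 16 and 16. With an estimated correlation they were 0, 1 and 2, and fry, which does not compare a list with other genes, called 31, 29 and 31. In fry 3 lists took the other direction from camera: NF-kB and cytokine genes in KO against WT (median -0.13, mean 0.04), ferroptosis drivers and markers in KO_BHB against KO (median -0.17), and mast cells, basophils and eosinophils in KO_BHB against WT (median -0.38). The signs of their members are mixed. Among genes called in either of the fits compared, the direction in KO_BHB against KO turned for Cd37 (0.10) and Ppbp (-0.30) with the GC and length trend taken out, and for Cd79b (-0.0504), Slc16a1 (-0.32), Hmgcl (-0.0723) and Acat1 (-0.12) with library size alone. In KO_BHB against WT it turned for Fas (-0.42) with the GC and length trend taken out. For the library size cases the shift of the median is enough, and for the others the cause was not tested. Of 505 named values, 487 kept their side of the threshold, and their direction if called, with library size alone and 484 with the GC and length trend taken out. Among these, 9 and 2 values that were called in neither fit changed sign, with Aifm2 in KO_BHB against KO (-0.12 with library size alone) as 1 of the 9. The alternatives planned for Hmgcs2 gave no value, because its reads were too few for a test. A count of 0 over all WT reads allows a level of up to 0.0276 CPM (95% exact Poisson interval). The labels do not say that the replicate numbers pair the samples, and no sign of pairing was seen. The deviations of same-numbered samples correlated at -0.0515 to 0.0778, 0 of 9 pairs above 0.1, and 3 of 9 samples matched their own number best. Such low values do not show that the samples were unpaired. With the replicate block 10823, 9335 and 13805 genes were called, 2609 in opposite ways, and 12, 16 and 15 lists. The lists no longer called were fatty acid oxidation (adjusted p 0.0516) and fatty acid synthesis and activation (0.0508) in KO against WT and p53 targets in KO_BHB against WT (0.0508).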

Other observations

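The tests with library size alone and with the GC and length trend taken out were chosen after the result was seen, and ENSMUSG00000119584, Ighm, Ddx3y and Xist after their values were seen. Single genes of cell death and stress passed the test in lists that were not called: apoptosis regulators in KO against WT and with BHB, p53 targets in KO against WT (camera adjusted p 0.204) and ATF4 targets with BHB. Of the apoptosis regulators 7 rose and 12 fell of 24 tested in KO against WT (camera adjusted p 0.306), with the survival gene Bcl2 higher (1.93 ± 0.13) and the death receptor Fas lower (-2.18 ± 0.0561). With BHB 9 rose and 7 fell of 24 tested (camera adjusted p 0.520), with the survival gene Mcl1 higher (1.32 ± 0.0627). Between KO and WT, of the replication genes 11 rose and 1 fell of 24 tested and of the mitotic genes 4 rose and 8 fell of 24 tested, with camera adjusted p of 0.05004 and 0.401. The replication list passed with RLE scaling (adjusted p 0.0382), with library size alone (0.0115), with no filter on low counts (0.0181), after the GC and length trend was taken out (0.0261), and without WT replicate 3 (0.0484) or KO replicate 3 (0.0333). The p53 target Phlda3 rose in KO (3.41 ± 0.13). Among ATF4 targets the median was -0.46 with BHB, and 5 rose and 11 fell of 22 tested, 5 and 12 adjusted over the list alone (camera adjusted p 0.107, and 0.00935 with no filter on low counts). The serine pathway enzyme Shmt2 fell (-1.43 ± 0.0752), and the stress regulator Nupr1 rose (1.80 ± 0.0502).

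Single iron genes passed as well, without a call of their list. The zinc and iron importer Slc39a14 rose in KO against WT (2.76 ± 0.18), the biliverdin reductase Blvra rose with BHB (0.91 ± 0.0653) and the ferrireductase Steap3 fell with BHB (-2.06 ± 0.15). The iron and heme list was not called with BHB (camera adjusted p 0.955), and 6 rose and 5 fell of 24 tested. With library size alone 4 rose and 15 fell, and the list was not called either. Markers of other marrow cells were not called as lists with BHB. Of mast cell, basophil and eosinophil genes 2 rose and 1 fell of 7 tested, 3 and 1 adjusted over the list alone, of plasma cell genes 2 rose and 1 fell of 8 tested, and of B lineage genes 1 rose and 3 fell of 7 tested, with camera adjusted p of 0.325, 0.570 and 0.466. The basophil protease Prss34 was at 0.205 ± 0.0356 CPM in WT, 0 in every KO library and 0.813 ± 0.227 in KO_BHB. Ighm, the heavy chain of the first antibody class, was at 106 ± 3.50, 111 ± 1.43 and 62.2 ± 6.00 CPM.

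An Ensembl gene that matched no symbol, ENSMUSG00000119584, took 1.73% ± 0.0130 of WT counts and 0.911% ± 0.0295 of KO_BHB counts. It ranked 6 by abundance in WT, 2 in KO and 4 in KO_BHB, and its identity was not analysed here. Ddx3y, a Y-linked gene, was at 68.6 ± 4.71 CPM in WT, 73.5 ± 6.99 in KO and 107 ± 9.90 in KO_BHB. Xist, the RNA of the inactive X chromosome, was at 0.304 ± 0.128, 2.65 ± 0.248 and 1.57 ± 0.136 CPM.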
